A study of Homo sapiens with 12 samples.

How the data were processed

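RNA was sequenced from primary esophageal fibroblasts of 4 human donors, each treated with vehicle, TGF-β1 (5 ng/ml) or LIGHT (50 ng/ml) for 24 hours after 16 hours without serum, 12 libraries in all. Per the labels, RNA was extracted with a miRNeasy Micro kit, selected for poly(A), and made into libraries with a NEBNext Ultra II Directional kit, which marks the strand. Per the submitters' processing notes, reads were aligned with Bowtie 1.0.0 and TopHat 1.4.1 and read counts per gene were made with HTSeq 0.7.1. The builds GRCh38 and mm10 are both listed there, with no role given to either. The strand setting of the counting and the annotation release are not given in the sources used here. The deposited values are raw counts per gene in 1 table of 58347 genes by 12 libraries, all matched to a sample.

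Gene identifiers were matched without their version to GENCODE 29 (GRCh38), which gave coordinates and symbols for 58084 of them; 256 symbols were used by more than 1 gene. Overlap of each gene's exons with exons on the opposite strand was measured with bedtools 2.31.1. Genes of the Y chromosome, XIST and TSIX (564) were left out of all tests. Library totals ran from 1445644 to 7830685 counts. CPM, counts scaled to a common library total, were computed with TMM factors and are given as mean ± SD over 4 libraries. No 2 libraries were copies: the lowest chi-square per degree of freedom over 66 pairs was 5.15. After removal of group means, 12 of 12 pairs of libraries from the same donor number correlated over 0.1 (0.169 to 0.500), and pairs from different donors lay between -0.296 and 0.109, so the donor was kept as a block.

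The tests used edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group, a model of group and donor with 6 residual degrees of freedom, common dispersion 0.0244) in R 4.3.3 on 13991 genes. LIGHT and TGF-β1 were each compared with vehicle and with each other, and genes at a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 changes are given with their standard error. Against a group with no count a fold is a lower bound from a floor of 3 counts over the group, and for 1 to 3 counts the ratio has an exact 95% counting interval. Lists of genes, 25 in all, were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated one, and their members were also adjusted over the list alone. The sizes given for lists are the members that passed the filter. MYH11, CNN1, ACTG2 and LMOD1 are in both the contractile and the smooth muscle list, so the results of these lists are not separate.

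The genes named are, per comparison, up to 12 with the largest rise and 12 with the largest fall among called protein-coding genes that changed the same way in 4 donors at a mean of at least 1 CPM, up to 4 members of each list with the smallest p, and a set of receptors, ligands and markers of both pathways; not every gene the rule allows is named. Groups, tests, lists, this rule and most alternatives were set before the data were examined. Genes outside the rule are marked in the text. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, no donor block, only the 8 libraries compared, each donor left out, library size alone, an estimated correlation and a minimum change of 2-fold. Leaving out the LIGHT library of donor 4, thinning all libraries to the shallowest, and keeping only genes without opposite-strand overlap were added after the data were seen.

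The procedure was tested on simulated data with the depths and dispersion of these libraries. For LIGHT, 60 of 94 genes changed 2-fold (63.8%) and 93 of 95 changed 4-fold (97.9%) were recovered, with 10 of 13351 unchanged genes called. For TGF-β1 69.1% and 90.6% were recovered, and for the direct comparison 65.6% and 87.2%. Few genes were changed in these simulations, as many upward as downward. They do not test the scaling where 52.2% (TGF-β1) or 53.1% (direct comparison) of genes were called, as in the real data. A changed list was called in each comparison, and 0 of 20 unchanged lists were. Genes were drawn independently in these simulations, so they do not test lists whose members vary together. Some other groupings of the real libraries gave as many list calls with the preset correlation as the real grouping, as described at the end. The estimated correlation was, for example, 0.298 for the extracellular matrix list with LIGHT. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.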

Results

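Gene expression was measured by poly(A)-selected RNA sequencing in primary fibroblasts cultured from the esophagus of 4 human donors. Cells of each donor were kept without serum for 16 hours and then received vehicle, TGF-β1 at 5 ng/ml or LIGHT at 50 ng/ml for 24 hours, which gave 3 groups of 4 libraries and 12 libraries in all. TGF-β1 is a cytokine that drives fibroblasts toward a contractile, matrix-producing state. LIGHT (TNFSF14) is a TNF superfamily cytokine that binds the lymphotoxin beta receptor (LTBR) and HVEM (TNFRSF14). Depth ranged from 1445644 to 7830685 counts per library. The vehicle libraries held 3.69e+06 ± 8.38e+05 counts (mean ± SD, n = 4), the LIGHT libraries 2.14e+06 ± 7.90e+05 and the TGF-β1 libraries 5.08e+06 ± 2.50e+06. A gene had at least 1 count in 22771 ± 789 cases per vehicle library and 21597 ± 1669 per TGF-β1 library (SD, n = 4). The LIGHT library of donor 4 stood apart, with 41398 such genes against 20290 to 22383 in the other 3 LIGHT libraries. The 10 most abundant genes took 20.2% ± 1.89 of the counts with TGF-β1, 12.7% ± 1.58 with vehicle and 11.2% ± 1.70 with LIGHT (SD, n = 4), and fibronectin (FN1) alone took 6.23% ± 1.09, 2.91% ± 0.865 and 2.03% ± 0.850. Along the first principal component (58.7% of the variance) the TGF-β1 libraries lay apart from the other 8, and the LIGHT library of donor 4 lay apart along the second (11.6%). The strand setting of the counting is not given for a kit that marks the strand. For all genes, with or without overlap, the levels and changes below thus rest on reads of an unstated strand. Counts of overlapping genes, given at the end, leave open that this is the strand holding fewer of a gene's reads.

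**Figure D1:**
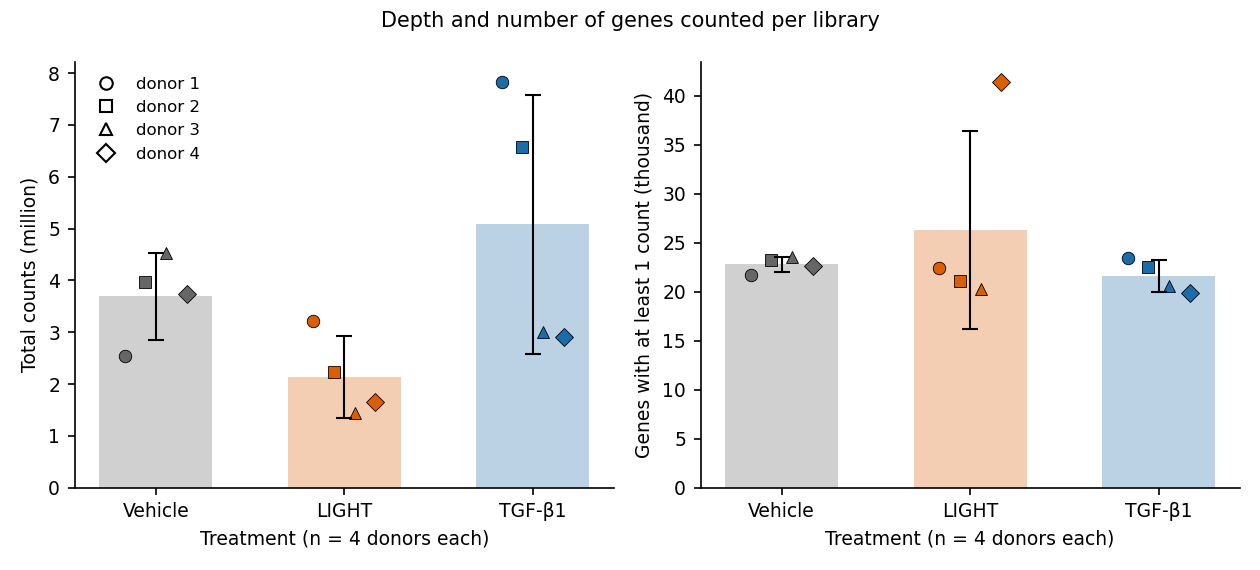
Total counts (left) and genes with at least 1 count (right) in each library, by treatment. Symbols are donors, bars are means and error bars are SD (n = 4); the LIGHT library of donor 4 held 41398 genes with a count, the other 11 at most 23498.

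The first comparison asked which genes LIGHT changed. NF-κB pathway genes rose as a group with LIGHT: 12 of the 21 tested rose, with a median log2 change of 0.89 over the list. NFKB2, a transcription factor subunit of the non-canonical NF-κB pathway (chromosome 10, 102394110 to 102402529, GRCh38), went from 35.1 ± 5.95 to 148 ± 41.2 CPM (mean ± SD, n = 4), a 4.15-fold rise (log2 change 2.05 ± 0.13 SE, adjusted p = 1.99e-07). Its partner RELB rose 4.29-fold, from 11.9 ± 2.87 to 54.1 ± 23.6 CPM (adjusted p = 9.48e-05). The adhesion molecules VCAM1 and ICAM1, the TNF receptor TNFRSF1B and several antigen presentation genes also rose, while 9 of 40 extracellular matrix genes fell. In total 512 of 13991 genes passed the threshold, 313 higher and 199 lower with LIGHT, and 117 of these changed at least 2-fold (102 higher, 15 lower).

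Within the NF-κB list, the antiapoptotic gene BIRC3 rose 20.7-fold (log2 change 4.37 ± 0.50, adjusted p = 0.000104), the receptor adaptor TRAF2 3.88-fold (adjusted p = 4.10e-06) and mitochondrial superoxide dismutase SOD2 4.18-fold (adjusted p = 3.75e-06). Adjusted over the list alone, 16 of its 21 members rose, and by DESeq2 10, with BIRC3 and NFKBIE set aside for a low mean count. The list as a set passed camera (adjusted p = 1.99e-36, and adjusted p = 0.00462 with an estimated correlation). Of 15 inflammatory cytokines and mediators, 4 rose, and 7 rose and 1 fell when adjusted over the list alone. DESeq2 called 3 of these 4 and set IL34 aside for a low mean count. The 4 were IL32 (7.79-fold, adjusted p = 9.05e-06), the macrophage growth factors IL34 (4.56-fold, adjusted p = 0.00392) and CSF1 (log2 change 0.58 ± 0.14, adjusted p = 0.0356), and complement C3 (3.41-fold, adjusted p = 0.000213). This list also passed as a set (adjusted p = 8.33e-06, and adjusted p = 0.0261 with an estimated correlation). IL6 stayed at 2.45 ± 1.89 CPM against 1.46 ± 0.764 with vehicle (adjusted p = 0.504), and CXCL8 had 26 counts in all 12 libraries and was not tested.

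Antigen presentation by MHC class I was represented by 16 genes, of which 4 rose and 7 rose when adjusted over the list alone. PSME2, a proteasome activator, rose 1.85-fold (adjusted p = 0.00105), the peptide transporter TAP1 1.79-fold (adjusted p = 0.00279), TAPBP 1.55-fold (adjusted p = 0.00736) and the immunoproteasome subunit PSMB10 by a log2 change of 0.97 ± 0.21 (adjusted p = 0.0167). As a set the list was higher (camera adjusted p = 1.12e-06), but not with an estimated correlation (adjusted p = 0.220). Of 17 TNF superfamily ligands and receptors, TNFRSF1B rose 2.99-fold, from 23.9 ± 7.12 to 71.4 ± 17.8 CPM (adjusted p = 1.29e-05). Adjusted over the list alone, 3 rose and 1 fell, and the set was higher (camera adjusted p = 0.0109; adjusted p = 0.329 with an estimated correlation). The receptors of LIGHT did not pass: TNFRSF14 was at 36.2 ± 12.6 CPM against 28.3 ± 8.79 (adjusted p = 0.253) and LTBR at 144 ± 28.8 against 142 ± 14.4. LIGHT itself, TNFSF14, had 34 counts in all libraries (2 with vehicle, 28 with LIGHT and 4 with TGF-β1) and was not tested. Of 9 leukocyte adhesion molecules, VCAM1 rose 2.10-fold (log2 change 1.07 ± 0.16, adjusted p = 0.00131) and ICAM1 2.88-fold (adjusted p = 0.00697), and ALCAM fell by 0.73 ± 0.17 on the log2 scale (adjusted p = 0.0264). Adjusted over the list alone the counts were also 2 and 1, the median (-0.15) and mean (0.17) differed in sign, and the set was not called (camera adjusted p = 0.415). None of the 9 lymphoid stroma and lymphocyte survival genes passed edgeR's test or DESeq2's (3 had an unadjusted p under 0.05, all higher, and 1 passed adjusted over the list alone; DESeq2 gave TNFSF13B no adjusted p). The B-cell survival factor TNFSF13B in this list was at 6.66 ± 1.74 CPM against 2.40 ± 1.10 (adjusted p = 0.0734), which became 0.00856 without the LIGHT library of donor 4, 0.00652 without donor 4 and 0.0447 with only the 8 libraries compared. The set was higher by camera (adjusted p = 0.0276), but not with an estimated correlation (adjusted p = 0.255).

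Extracellular matrix genes made up the largest list that fell with LIGHT: 9 of 40 fell, or 18 when adjusted over the list alone (1 rose), and the median log2 change was -0.37. Examples were versican (VCAN, log2 change -1.08 ± 0.22, adjusted p = 0.0125), COL15A1 (55.7 ± 31.1 to 28.7 ± 19.5 CPM, adjusted p = 0.0195), fibrillin 1 (FBN1, -0.91 ± 0.19, adjusted p = 0.0167) and COL8A1 (-0.79 ± 0.17, adjusted p = 0.0161). COL1A1, the main type I collagen chain, did not pass (log2 change -0.50 ± 0.15, adjusted p = 0.0762; DESeq2 adjusted p = 0.00941). The set was lower by camera (adjusted p = 1.77e-08, and 3.47e-05 without the LIGHT library of donor 4), but not with an estimated correlation (adjusted p = 0.329). In that library the median of the list was -0.86 against -0.31 to -0.14 in the other donors. TGF-β pathway components were lower as a set (20 tested, camera adjusted p = 0.000861; adjusted p = 0.255 with an estimated correlation), with 1 member called, the co-receptor TGFBR3 (log2 change -0.82 ± 0.17, adjusted p = 0.0156), and 3 lower when adjusted over the list alone. The receptor TGFBR2 was at -0.59 ± 0.17 (adjusted p = 0.0612), and was called lower without the filter (0.0159), with DESeq2 (0.0291), with only 8 libraries (0.0350) and thinned (0.0293). BMP response genes were also lower as a set (11 tested, camera adjusted p = 0.00758; adjusted p = 0.359 with an estimated correlation), with BMP6 called (-1.02 ± 0.25, adjusted p = 0.0304) and 5 lower adjusted over the list alone. Of 17 genes of serine, glycine and proline synthesis, 0 passed edgeR's test over all genes or over the list alone, 7 had an unadjusted p under 0.05 and 2 passed DESeq2's, all lower. That set was lower by camera (adjusted p = 0.000861), but not with an estimated correlation (adjusted p = 0.423).

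The remaining lists were not called with LIGHT, but without the filter the contractile (adjusted p = 1.99e-07), endoplasmic reticulum stress (1.45e-05), glycolysis (0.000492), quiescent (0.00513) and protease lists (0.0397) were called lower, the last also with only the 8 libraries compared (0.0467). Without the filter the median log2 change of all genes was 0.79, and camera compares a list with the other genes. Those calls alone thus do not show a fall of these lists. Among 19 TGF-β response genes, JUNB rose 2.17-fold (adjusted p = 0.000733) and CTGF, a matricellular protein gene, fell by 1.16 ± 0.19 on the log2 scale (adjusted p = 0.00230); 2 rose and 1 fell adjusted over the list alone, and the list's median (-0.13) and mean (0.09) differed in sign. None of 23 contractile and myofibroblast genes passed edgeR's test, over all genes or over the list alone (5 had an unadjusted p under 0.05 and 2 passed DESeq2's, all lower). Smooth muscle actin (ACTA2) was at 228 ± 60.1 CPM against 215 ± 52.3 (log2 change 0.06 ± 0.15, adjusted p = 0.854). SYNPO2, an actin-binding protein of smooth muscle, fell by 1.34 ± 0.21 on the log2 scale (adjusted p = 0.00174), alone of 9 smooth muscle markers; 2 fell adjusted over the list alone, the median (-0.11) and mean (0.11) differed in sign, and the set (camera adjusted p = 0.176) was called lower without the LIGHT library of donor 4 (adjusted p = 0.0226). Of 7 inflammatory chemokines, 0 passed edgeR's test or DESeq2's (which gave CXCL5 no adjusted p), and 2 had an unadjusted p under 0.05 and were higher adjusted over the list alone. CXCL5 was at 2.93-fold (adjusted p = 0.0548) and CCL2 at 1.48-fold (adjusted p = 0.0777). Both were called higher with only 8 libraries (0.0288 and 0.0353) and by library size alone (0.0419 and 0.0430), and CCL2 also thinned (0.0219). The interferon-inducible regulator IRF1 rose 1.55-fold (adjusted p = 0.0403) among 31 interferon-stimulated genes, but was not called without the filter (0.240), with DESeq2 (0.0519), thinned (0.117) or without the donor block (0.298). The protease CTSS rose 6.11-fold (adjusted p = 0.00921) and tissue plasminogen activator PLAT fell by 0.72 ± 0.19 on the log2 scale (adjusted p = 0.0423; thinned 0.117, by library size alone 0.0514) among 17 matrix proteases and inhibitors. Adjusted over the list alone, 1 interferon-stimulated gene rose, and 2 proteases or inhibitors rose and 4 fell. EGLN3, an oxygen-sensing hydroxylase, rose 18.0-fold (adjusted p = 0.00701) among 21 glycolysis and hypoxia genes, the same count as over the list alone, with a median of -0.12 and a mean of 0.11. Its log2 change of 4.17 was 3.32 without the LIGHT library of donor 4, 3.14 without donor 4 and 4.80 without donor 2, and it was not called without donor 1 (adjusted p = 0.0612). DESeq2 called no gene of this list and set EGLN3 aside for a low mean count (unadjusted p = 2.82e-06). No member of the lists for the cell cycle (20), endoplasmic reticulum stress (20), cholesterol synthesis (19) or quiescent fibroblasts (19) passed edgeR's test. At an unadjusted p under 0.05 these lists had 2, 3, 1 and 5 members, and DESeq2 called 2 of the quiescent list and 0 of the others; adjusted over the list alone, 4 quiescent genes fell. Nor did any of 2 epithelial, 3 endothelial, 1 leukocyte or 4 pericyte and Schwann cell markers pass, with 0 at an unadjusted p under 0.05 and 0 by DESeq2.

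Outside the lists, OR2I1P, annotated as an olfactory receptor gene (chromosome 6, 29550407 to 29557721, plus strand, GRCh38), had the largest rise among named genes, from 0.449 ± 0.430 to 140 ± 134 CPM (log2 change 8.10 ± 0.30, adjusted p = 8.15e-11). Its exons overlap those of opposite-strand genes over 15.6% of their length, and its counts are therefore uncertain. They may belong to a gene on the opposite strand, as described at the end. TAC3, which encodes neurokinin B, rose 15.7-fold (adjusted p = 0.00117), the phospholipase PLA2G4C 8.51-fold (adjusted p = 2.12e-05) and TRIM47 8.08-fold (adjusted p = 3.44e-06), the last with 51.5% of its exons overlapped on the opposite strand. The insulin-like growth factor binding protein IGFBP3 fell by 1.27 ± 0.20 on the log2 scale (adjusted p = 0.00195). All genes named as called with LIGHT changed the same way in 4 of 4 donors.

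Of the 313 genes higher with LIGHT, 75.7% had exons overlapped by exons on the opposite strand, against 49.5% of all genes tested and 40.2% of the 199 lower genes. Among genes without such overlap 76 were higher and 119 lower, and with only those genes fitted 72 were higher and 32 lower. ICAM1 (23.6%), IRF1 (22.0%), JUNB (14.2%), TAP1 (9.49%) and CTGF (8.34%) have part of their exons overlapped in this way. So do other genes named above or below, among them IL6 (20.7%), PSMB8 (20.6%), TNFRSF14 (13.4%) and THY1 (10.7%). The overlap is not given for every named gene. Genes annotated as antisense took 10.1% ± 1.47 of the counts with LIGHT, 7.51% ± 0.456 with vehicle and 7.71% ± 0.697 with TGF-β1 (SD, n = 4). Without the donor as a block, 78 genes passed (74 higher, 4 lower), and 19 called genes named above did not: C3, IL34, CSF1, VCAM1, ICAM1, ALCAM, TAP1, PSMB10, IRF1, TAC3, SYNPO2, IGFBP3, VCAN, FBN1, COL8A1, COL15A1, TGFBR3, BMP6 and PLAT (adjusted p 0.0737 to 0.555). CSF1 and TAPBP were not called without the filter (0.172 and 0.0858), nor were ALCAM, BMP6 and PLAT with only genes without overlap fitted (0.0712, 0.0712 and 0.0948). With the libraries of donor 1, 2 or 3 left out in turn, 89, 118 and 169 passed, and without donor 4 440 passed. Of the called genes named above, 15 missed the threshold without donor 1 (IL34, CSF1, ALCAM, TAP1, TAPBP, PSMB10, IRF1, CTSS, EGLN3, FBN1, COL8A1, COL15A1, TGFBR3, BMP6 and PLAT, adjusted p 0.0542 to 0.196). Without donor 2 there were 10 (CSF1, ALCAM, TAPBP, PSMB10, IRF1, CTSS, FBN1, COL8A1, BMP6 and PLAT, 0.0513 to 0.189), without donor 3 8 (ALCAM, TAPBP, PSMB10, IRF1, VCAN, COL15A1, BMP6 and PLAT, 0.0656 to 0.102) and without donor 4 5 (CSF1, ALCAM, IRF1, BMP6 and PLAT, 0.0586 to 0.0938). The TNF superfamily list was not called without donor 1 or 2 (adjusted p = 0.0703 and 0.0630) or without the filter (0.210), nor the lymphoid stroma list without donor 3 (0.0712), without the filter (0.420) or thinned (0.213). The chemokines were called higher without donor 3 or 4 (0.0241 and 0.0496) and, without donor 2, the contractile (0.00536) and endoplasmic reticulum stress genes (0.04997) were called lower. Without the LIGHT library of donor 4 alone, 383 passed (297 higher, 86 lower) and 6 genes named above missed the threshold: CSF1 (adjusted p = 0.0697), ALCAM (0.0753), IRF1 (0.0792), COL15A1 (0.0529), BMP6 (0.0727) and PLAT (0.0910). DESeq2 gave no adjusted p to 7 called genes named above, set aside for a low mean count: BIRC3, PLA2G4C, EGLN3, IL34, CTSS, TAC3 and PSMB10 (unadjusted p 4.17e-15 to 0.000419). Scaling by library size alone gave 459 higher and 133 lower genes, 77.5% higher against 61.1%.

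**Figure D2:**
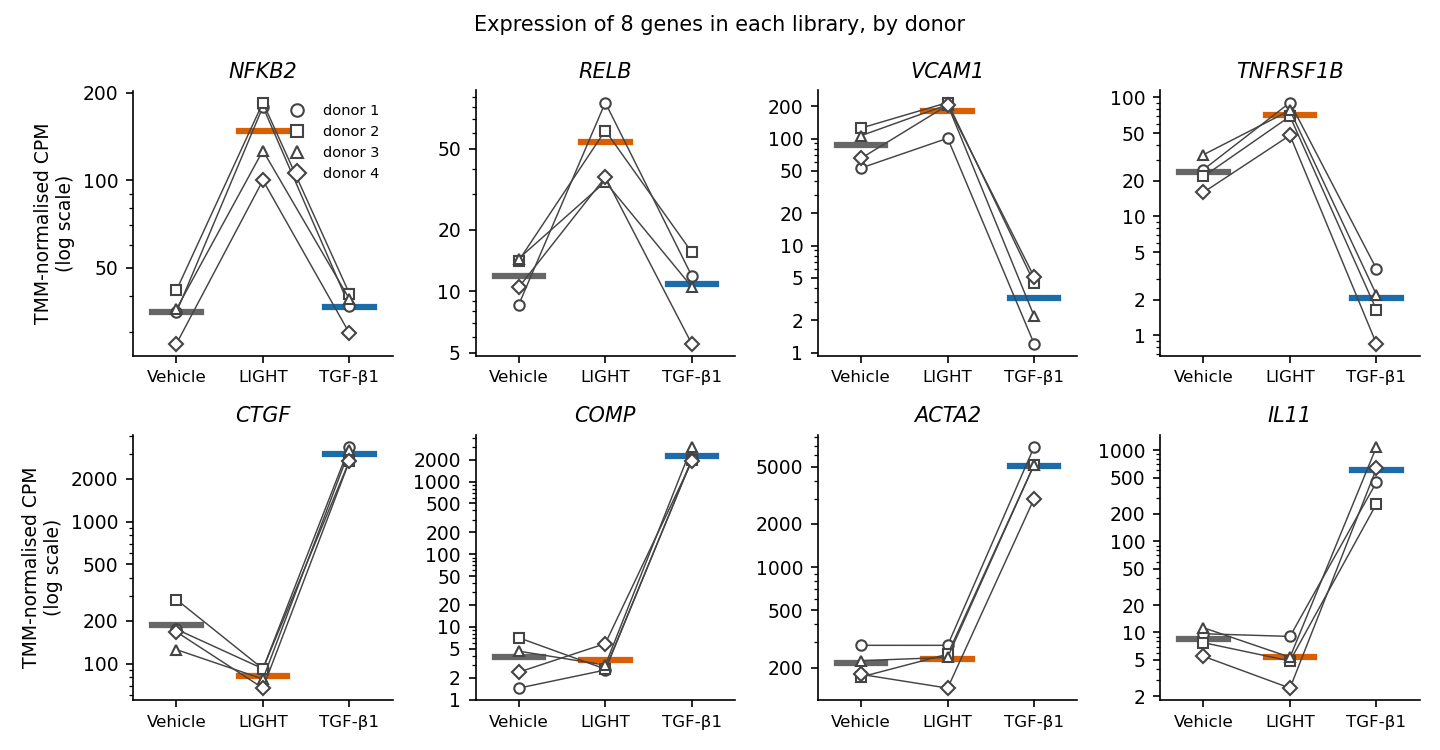
TMM-normalised CPM (log axis) of 8 genes in each library; symbols joined by lines are donors and coloured bars are group means (n = 4). NFKB2 and RELB rose with LIGHT and were not called with TGF-β1, VCAM1 and TNFRSF1B rose with LIGHT and fell with TGF-β1, and CTGF, COMP, ACTA2 and IL11 rose with TGF-β1.

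The second comparison asked which genes TGF-β1 changed. TGF-β1 raised all 19 TGF-β response genes and all 23 contractile and myofibroblast genes tested. Cartilage oligomeric matrix protein (COMP, chromosome 19, 18782773 to 18791314, GRCh38) rose 549-fold, from 3.88 ± 2.52 to 2224 ± 524 CPM (mean ± SD, n = 4; log2 change 9.10 ± 0.30 SE, adjusted p = 2.77e-12). ACTA2 rose 22.8-fold, from 215 ± 52.3 to 5049 ± 1589 CPM (adjusted p = 9.16e-12), with 30.1% of its exons overlapped on the opposite strand. All 7 inflammatory chemokines fell, as did VCAM1, 27.5-fold in size (log2 change -4.78 ± 0.24, adjusted p = 1.22e-10). In total 7297 of 13991 genes passed, 3775 higher and 3522 lower, and 3595 of them changed at least 2-fold (1735 higher, 1860 lower).

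TGF-β response genes had a median log2 change of 3.96 and were higher as a set (camera adjusted p = 6.88e-40, and adjusted p = 0.000740 with an estimated correlation); the same 19 rose adjusted over the list alone. CTGF rose 16.3-fold (adjusted p = 1.15e-10), the tetraspanin TSPAN2 62.6-fold (adjusted p = 8.70e-12) and the inhibitory SMAD7 3.94-fold (adjusted p = 3.14e-07). Contractile genes had a median of 2.26 (camera adjusted p = 4.56e-33; adjusted p = 0.0633 with an estimated correlation), and all 23 also rose adjusted over the list alone. Calponin (CNN1) rose 49.5-fold, from 24.3 ± 4.42 to 1213 ± 267 CPM, and the enteric actin ACTG2 33.4-fold. Of 9 smooth muscle markers 7 rose, over all genes and adjusted over the list alone, among them desmin (DES, 32.1-fold, adjusted p = 1.11e-10) and phospholamban (PLN), which had no count with vehicle and was at least 128-fold higher with TGF-β1 against a floor of 3 counts over the group. That set was higher (camera adjusted p = 5.94e-11; adjusted p = 0.0633 with an estimated correlation). The citrullinating enzyme PADI2, also without a vehicle count, was at least 79.7-fold higher.

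Of 40 extracellular matrix genes 31 rose and 4 fell, over all genes and adjusted over the list alone, with a median of 1.62. Elastin (ELN) rose 33.3-fold, from 448 ± 239 to 14821 ± 7415 CPM (adjusted p = 2.21e-11), biglycan (BGN) 10.7-fold, the crosslinking enzyme LOX 8.07-fold and COL1A1 3.31-fold, from 15779 ± 3178 to 51329 ± 3121 CPM (adjusted p = 1.14e-07). POSTN rose 1.79-fold (adjusted p = 0.0143), but not without donor 2 (adjusted p = 0.174), without the donor block (adjusted p = 0.213) or scaled by library size alone (adjusted p = 0.349). The 4 that fell, named after their values were seen, were COL6A1 (-0.54 ± 0.13), FBLN1 (-1.11 ± 0.15), decorin (DCN, -1.25 ± 0.18) and lumican (LUM, -1.61 ± 0.17), as log2 changes. The matrix list was higher as a set (camera adjusted p = 1.92e-15; adjusted p = 0.107 with an estimated correlation). All 20 endoplasmic reticulum stress genes rose, with a median of 1.49, including the chaperone HSPA5 (3.64-fold, adjusted p = 1.80e-08) and XBP1 (3.72-fold, adjusted p = 1.07e-08); the set passed camera (adjusted p = 3.68e-12; adjusted p = 0.0985 with an estimated correlation).

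Metabolic lists rose as well. Of 21 glycolysis and hypoxia genes 18 rose, among them the glucose transporter SLC2A1 (32.7 ± 9.70 to 264 ± 86.0 CPM, adjusted p = 8.94e-10), PFKP (6.14-fold, adjusted p = 2.14e-10) and VEGFA (4.58-fold, adjusted p = 1.63e-09), and 2 fell, ADM (log2 change -2.27 ± 0.21) and ANGPTL4 (-4.28 ± 0.28), both named after their values were seen. The set was higher (camera adjusted p = 1.53e-10; adjusted p = 0.0922 with an estimated correlation). In serine, glycine and proline synthesis 16 of 17 rose, including the amino acid transporter SLC7A5 (14.2-fold, adjusted p = 5.87e-11), and SHMT1 fell (-1.22 ± 0.31, not called thinned, adjusted p = 0.0631; named after its values were seen). That set was higher by camera (adjusted p = 2.98e-08; adjusted p = 0.138 with an estimated correlation). Of 19 cholesterol synthesis genes 15 rose, such as SQLE (3.88-fold, adjusted p = 3.35e-07), and LSS fell (-1.06 ± 0.14, adjusted p = 7.71e-06), with a set test of adjusted p = 0.0130 by camera and adjusted p = 0.475 with an estimated correlation. For the stress and metabolic lists the counts were the same adjusted over the list alone.

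The 7 chemokines that fell, also adjusted over the list alone, included CCL2 (-4.13 ± 0.27, adjusted p = 2.41e-09) and the eosinophil attractant CCL11 (-4.45 ± 0.40, adjusted p = 1.00e-07), as log2 changes; the set passed camera (adjusted p = 0.00129; adjusted p = 0.175 with an estimated correlation). Of 31 interferon-stimulated genes 21 fell, for example IFIT1 (-4.76 ± 0.35, adjusted p = 1.12e-08), while GBP1 (3.72-fold) and XAF1 (4.52-fold, 38.3% of exons overlapped on the opposite strand) rose, and the set was lower (camera adjusted p = 0.00277; adjusted p = 0.0633 with an estimated correlation). Of 16 MHC class I presentation genes 9 fell, among them the immunoproteasome subunits PSMB8 (-2.86 ± 0.20) and PSMB9 (-2.75 ± 0.27) and the MHC gene HLA-E (-1.42 ± 0.17), and the set was lower (camera adjusted p = 0.00636; adjusted p = 0.350 with an estimated correlation). The counts of both lists were the same adjusted over the list alone. Inflammatory cytokines went both ways, with 6 higher and 7 lower of 15 (6 and 8 adjusted over the list alone), a median of -0.68, a mean of 0.38 and a set test of adjusted p = 0.501. IL11 rose 66.0-fold, from 8.54 ± 2.51 to 607 ± 357 CPM (adjusted p = 1.27e-10), LIF 27.7-fold (adjusted p = 3.31e-11) and IL6 10.1-fold (adjusted p = 2.58e-06), while CSF1 fell (-2.54 ± 0.16, adjusted p = 2.43e-09). CCL11 was at -3.86 without donor 1 and IFIT1 at -5.39 without donor 3, both still called.

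Other lists were not called as sets by camera with TGF-β1, but without the filter the NF-κB (adjusted p = 0.00765) and lymphoid stroma lists (0.00103) were called lower and the TGF-β pathway components higher (0.00253). Without the filter the median log2 change of all genes was 0.15. Of 17 TNF superfamily genes 10 fell, including TNFRSF1B (-3.41 ± 0.23) and the LIGHT receptors TNFRSF14 (-3.10 ± 0.22, adjusted p = 6.09e-09) and LTBR (-0.79 ± 0.14, adjusted p = 0.000199). The 5 that rose were TNFRSF12A (9.83-fold), TNFSF4 (6.73-fold), TNFRSF11B (5.05-fold), TNFRSF10D (3.26-fold) and TNFSF18 (3.03-fold), the last 4 named after their values were seen. TNFSF18 was not called without donor 4 (log2 change 0.70, adjusted p = 0.232), without donor 2 (0.0535), without the donor block (0.0552) or by library size alone (0.0931). It was at 2.21 without donor 3. The list had 6 higher and 10 lower genes adjusted over itself alone (set adjusted p = 0.140). Among 21 NF-κB pathway genes 8 fell, such as TRAF1 (-1.82 ± 0.21), NFKBIA (-1.47 ± 0.19) and SOD2 (-1.44 ± 0.18), and RELA rose 1.36-fold (log2 change -0.11 scaled by library size alone, adjusted p = 0.466; not called without donor 2, adjusted p = 0.118, without the donor block, 0.0827, or without the filter, 0.0865; named after its values were seen), with a set test of adjusted p = 0.101. NFKB2 (0.05 ± 0.14, adjusted p = 0.795; scaled by library size alone -0.51, adjusted p = 0.00357) and RELB (-0.21 ± 0.27, adjusted p = 0.544; scaled by library size alone -0.77, adjusted p = 0.0145) did not pass. Of 9 lymphoid stroma genes 4 fell: CXCL12 (-3.34 ± 0.21), BST1 (-0.78 ± 0.24), MADCAM1 (-1.29 ± 0.43) and TNFSF13B, which was 12.3 times higher with vehicle (95% exact counting interval 3.91 to 62.1; 40 counts against 3), with a set test of adjusted p = 0.0538. Of 9 leukocyte adhesion molecules 5 fell, VCAM1, F11R (-2.18 ± 0.31), CD47 (-1.06 ± 0.13) and, named after their values were seen, CD44 (-1.16 ± 0.21) and THY1 (-0.88 ± 0.14), and 2 rose, MCAM (6.87-fold) and ICAM3 (log2 change 0.68 ± 0.16, 71.2% of exons overlapped on the opposite strand, named after its values were seen), with a set test of adjusted p = 0.0545. ICAM1 did not pass (0.30 ± 0.30, adjusted p = 0.434). Adjusted over the list alone, the counts of these 3 lists (NF-κB, lymphoid stroma and adhesion) were the same. MADCAM1 was not called without donor 1, 2 or 3 (adjusted p = 0.0814, 0.0649 and 0.0544), BST1 without donor 2 (0.0639) or thinned (0.0850), nor ICAM3 by library size alone (0.547). The fitted log2 change of TNFSF13B was -4.12 without donor 4, against -3.34. The adhesion list was called lower without the LIGHT library of donor 4 (adjusted p = 0.0404) and the lymphoid stroma list without donor 3 (0.0295).

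Of 20 TGF-β pathway components 9 rose, such as TGFBR1 (6.52-fold, adjusted p = 2.98e-08) and the activin subunit INHBA (17.2-fold, adjusted p = 5.31e-10), and 4 fell: TGFBR3 (-4.05 ± 0.22), SMAD3 (-2.15 ± 0.14), TGFBR2 (-1.77 ± 0.17) and LTBP4 (-0.77 ± 0.16, named after its values were seen), with a set test of adjusted p = 0.140. Of 11 BMP response genes BMP6 (5.22-fold) and ID4 (2.23-fold) rose and BMP4 (-3.62 ± 0.23), ID2 (-1.70 ± 0.18), SMAD6 (-1.48 ± 0.25) and SMAD9 (-1.22 ± 0.22) fell (set adjusted p = 0.101; ID4 and SMAD9 named after their values were seen). Of 17 matrix proteases and inhibitors 9 fell, such as the aggrecanase ADAMTS5 (-4.35 ± 0.36), and TIMP3 (9.58-fold), TIMP1 (5.75-fold), MMP3 (4.07-fold) and ADAMTS4 (2.47-fold) rose (set adjusted p = 0.111; MMP3 and ADAMTS4 named after their values were seen). Of 20 cell cycle genes 10 fell, such as TPX2 (-1.89 ± 0.33) and TYMS (-1.85 ± 0.18, 46.6% of exons overlapped on the opposite strand), and CCNA2 (1.82-fold) and CCNB2 (1.95-fold) rose, both named after their values were seen. CCNB2 was not called without donor 1, 2 or 3 (adjusted p = 0.156, 0.210 and 0.0599), without the donor block (0.211), with RLE factors (0.0516), with DESeq2 (0.0653), without the filter (0.0943) or by library size alone (0.362). CCNA2 was not called by library size alone (0.215). The cell cycle set (adjusted p = 0.0513) was called lower without donor 1, 2 or 3 (0.0286, 0.0497 and 0.0295), without the donor block (0.0141), without the filter (5.35e-06) and without the LIGHT library of donor 4 (0.0378). Of 19 quiescent fibroblast genes 8 fell, such as ADH1B (-5.16 ± 0.30) and PDGFRA (-2.92 ± 0.29), and PI16 (25.9-fold), MFAP5 (9.01-fold) and CLU (1.33-fold, but -0.14 on the log2 scale by library size alone, named after its values were seen) rose (set adjusted p = 0.221). Adjusted over the list alone, these 5 lists gave the same counts. Among markers of other cell types, DSP (4.77-fold) was the 1 of 2 epithelial markers that rose, ERG (6.05-fold) rose and VWF (-2.74 ± 0.56) fell among 3 endothelial markers, CD68 (-1.73 ± 0.38) fell as the only leukocyte marker tested, and in the 4 pericyte and Schwann cell markers NOTCH3 (3.78-fold) and CSPG4 (2.45-fold) rose and KCNJ8 (-2.43 ± 0.48) and ABCC9 (-2.58 ± 0.63) fell, where the median (-0.57) and mean (-0.45) had the opposite sign to the set test (adjusted p = 0.455). Camera gave an adjusted p of 0.646, 0.668 and 0.409 for the epithelial, endothelial and leukocyte lists. DSP was not called without donor 1 or 3 (adjusted p = 0.152 and 0.0696), without the donor block (0.0580), with DESeq2 (0.144) or by library size alone (0.0823). Its log2 change of 2.25 was 3.18 without donor 2, and without donor 4 it was not tested. ADAMTS4 was not called without donor 3 (0.204), without the donor block (0.0739), with DESeq2 (0.149) or by library size alone (0.221). Without donor 1 it was at 1.90, against 1.30. CLU was not called without donor 3 or 4 (0.108 and 0.0506), without the donor block (0.228), without the filter (0.141) or by library size alone (0.390). LTBP4 and KCNJ8 were not called without the donor block (0.133 and 0.0775), nor ID4 by library size alone (0.0709). MMP3 was at 1.44 without donor 2, ADAMTS5 at -5.09 and ERG at 3.24 without donor 3, all still called.

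Among the largest changes outside the lists, HBEGF, an epidermal growth factor family ligand, rose 108-fold (adjusted p = 9.26e-11). The vitamin D hydroxylase CYP24A1 was 358 times higher with vehicle than with TGF-β1 (95% exact counting interval 98.8 to 2962), the pyruvate dehydrogenase kinase PDK4 302 times (83.2 to 2498) and TMEM37 158 times (43.4 to 1310), each with 2 counts in the TGF-β1 group. The iron exporter SLC40A1 (-6.06 ± 0.27) and the tight junction gene CLDN11 (-5.33 ± 0.20) fell in 4 of 4 donors. These intervals and floors cover counting error only. The fitted log2 change of CYP24A1 (-8.03) was -6.37 without donor 2, -8.80 without donor 1 and -8.65 without donor 3, and that of PDK4 (-7.88) was -8.47 without donor 4. Scaled by library size alone, 1724 genes were higher and 7463 lower with TGF-β1, 18.8% higher against 51.7%, with a median of all genes of -0.56 on the log2 scale, and the folds given here are relative to that shift.

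**Figure D3:**
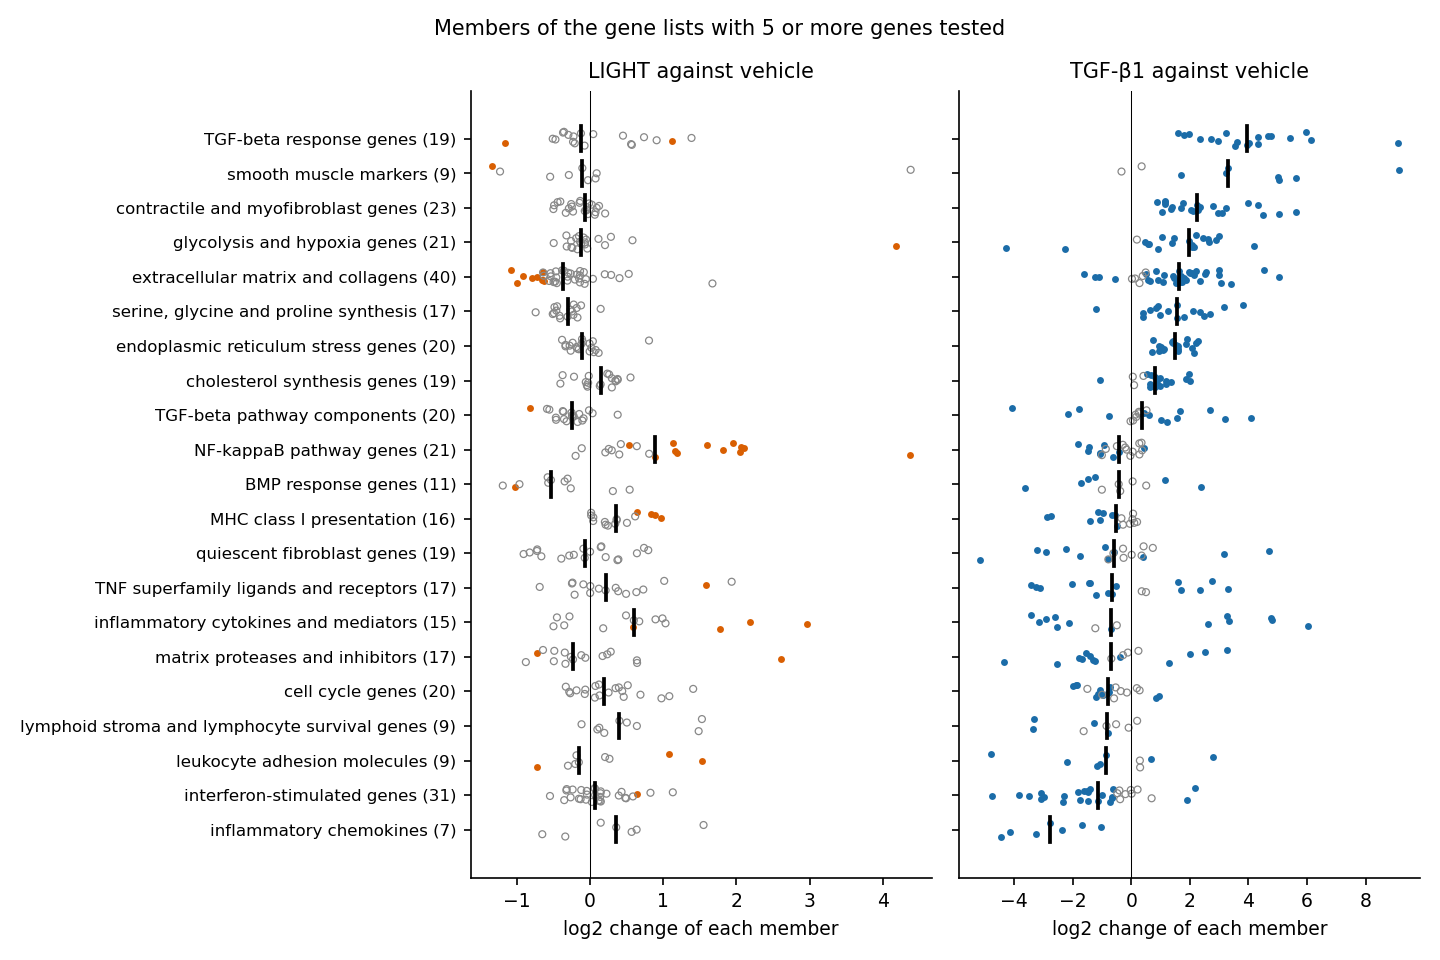
Log2 change of each member of the 21 gene lists with at least 5 genes tested, with LIGHT (left) and TGF-β1 (right) against vehicle. Filled points passed the test over all 13991 genes, open points did not, black lines are list medians and numbers in parentheses are genes tested; the NF-κB list had a median of 0.89 with LIGHT and the TGF-β response list 3.96 with TGF-β1.

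The third comparison set LIGHT directly against TGF-β1, at doses that were not matched. All 19 TGF-β response genes, all 23 contractile genes and 32 of 40 matrix genes were higher with TGF-β1. All 7 chemokines, 16 of 21 NF-κB, 13 of 16 antigen presentation and 23 of 31 interferon-stimulated genes were higher with LIGHT. As sets, only the TGF-β response list kept its call with an estimated correlation (adjusted p = 0.00743; 0.0543 to 0.113 for the other 6). VCAM1 was 57.7-fold higher with LIGHT (182 ± 54.8 against 3.25 ± 1.85 CPM, n = 4, adjusted p = 1.74e-11), TNFRSF1B 31.8-fold (adjusted p = 3.24e-11) and CCL2 25.9-fold (adjusted p = 5.22e-10). COMP was lower with LIGHT by a log2 change of -9.31 ± 0.31 (adjusted p = 6.75e-12), IL11 by -6.55 ± 0.33 (adjusted p = 1.72e-10) and IGFBP3 by -5.88 ± 0.23 (adjusted p = 1.62e-11). Of 13991 genes 7427 differed, 3632 higher and 3795 lower with LIGHT, and 3789 by at least 2-fold (2055 higher, 1734 lower).

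All 19 TGF-β response genes were lower with LIGHT than with TGF-β1, for example CTGF (-5.19 ± 0.21) and SMAD7 (-1.94 ± 0.21), and this set was called by camera with the preset and with an estimated correlation (adjusted p = 6.72e-39 and 0.00743). All 23 contractile genes were lower, such as CNN1 (-5.56 ± 0.15) and ACTA2 (-4.45 ± 0.17), and 32 of 40 matrix genes, such as ELN (-5.78 ± 0.22) and COL1A1 (-2.23 ± 0.16); COL6A1 (0.48 ± 0.13), FBLN1 (0.80 ± 0.15), DCN (0.79 ± 0.18) and LUM (1.34 ± 0.17) were higher and were named after their values were seen. Both sets were lower (adjusted p = 7.97e-38 and 2.95e-23; adjusted p = 0.0543 for each with an estimated correlation), as were 8 of 9 smooth muscle markers (adjusted p = 9.75e-13; adjusted p = 0.0543 with an estimated correlation). All 20 endoplasmic reticulum stress genes were lower with LIGHT, such as HSPA5 (-1.98 ± 0.14), with adjusted p = 2.88e-13 for the set and adjusted p = 0.0797 with an estimated correlation. The sets for serine, glycine and proline synthesis (16 of 17 lower, such as SLC7A5 at -4.06 ± 0.18; SHMT1 higher at 1.36 ± 0.32) and for glycolysis and hypoxia (17 of 21 lower, such as PFKP at -2.50 ± 0.14; ADM and ANGPTL4 higher at 2.10 ± 0.22 and 4.03 ± 0.28) were lower too, with adjusted p = 2.09e-11 and 4.91e-11, and adjusted p = 0.0797 and 0.0543 with an estimated correlation. SHMT1, ADM and ANGPTL4 were named after their values were seen. Cholesterol synthesis genes (12 of 19 lower, LSS higher at 1.44 ± 0.14) and TGF-β pathway components (11 of 20 lower, such as TGFBR1 at -3.26 ± 0.23, while TGFBR2 was higher at 1.18 ± 0.18) gave adjusted p = 0.0358 and 0.0110, and adjusted p = 0.529 and 0.212 with an estimated correlation. The cholesterol list was not called without donor 1 or 2 (adjusted p = 0.0735 and 0.0663) or thinned to the shallowest library (0.0989). COL6A1 was not called without donor 1 or 3 (0.0621 and 0.0646) or without the filter (0.118). The protease inhibitor TIMP1 was lower as well (-2.24 ± 0.15).

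Of 21 NF-κB pathway genes 16 were higher with LIGHT (17 adjusted over the list alone), among them SOD2 (11.4-fold), NFKBIA (6.21-fold), RELB (4.95-fold) and NFKB2 (4.01-fold), and RELA was lower (-0.56 ± 0.15, but 0.058 scaled by library size alone, adjusted p = 0.724; named after its values were seen), with adjusted p = 2.32e-09 for the set and adjusted p = 0.0762 with an estimated correlation. All 7 chemokines, 6 of 9 lymphoid stroma genes, such as CXCL12 (10.9-fold), and 13 of 16 MHC class I genes, such as PSMB9 (10.3-fold) and TAPBP (3.39-fold), were higher. These sets gave adjusted p = 0.000126, 0.00595 and 4.71e-06, and adjusted p = 0.0948, 0.0797 and 0.113 with an estimated correlation. Of 31 interferon-stimulated genes 23 were higher, such as IFIT1 (18.5-fold), and others, such as GBP1 (-2.25 ± 0.17) and XAF1 (-2.12 ± 0.15), were lower, with adjusted p = 0.000746 for the set and adjusted p = 0.0543 with an estimated correlation. TNF superfamily genes (10 of 17 higher, among them TNFRSF14, log2 change 3.45 ± 0.22, and LTBR, 0.79 ± 0.14), adhesion molecules (6 of 9 higher, ICAM1 2.35-fold) and cell cycle genes (12 of 20 higher) gave adjusted p = 0.0191, 0.0282 and 0.0110, and adjusted p = 0.385, 0.0948 and 0.0762 with an estimated correlation. ICAM1 was not called without the donor block (adjusted p = 0.0534), RELA without donor 2 (0.0506), the adhesion list without donor 1 or 2 (0.0562 and 0.132), without the donor block (0.0773) or without the filter (0.654), nor the TNF superfamily list without donor 2 (0.0782). The other 8 lists were not called. Cytokines went both ways, with CSF1 8.68-fold higher and LIF (-4.19 ± 0.20) and IL6 (-2.67 ± 0.40) lower with LIGHT, and IL32, higher with either cytokine, was not called (1.28-fold, adjusted p = 0.187, by library size alone 0.00120; named after its values were seen). The quiescence gene ADH1B was 46.4-fold higher. OR2I1P had 1358 counts with LIGHT and 2 with TGF-β1, a ratio of 1047 (95% exact counting interval 289 to 8656). Its fitted log2 change of 9.65 was 11.27 without donor 2, and that of IFIT1 (4.21) was 4.80 without donor 3. Apart from the NF-κB and quiescent lists (7 higher over all genes, 10 over the list alone), the counts were the same adjusted over the list alone. Scaled by library size alone, 7912 genes were higher and 1582 lower with LIGHT, 83.3% higher against 48.9%, with a median of all genes of 0.64.

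Among the 512 genes called with LIGHT, 219 were called in the same direction with TGF-β1 and 128 in the opposite direction, and 165 were not called with TGF-β1. Independent lists of these sizes would share 134.5 and 132.5 genes. By direction, 121 genes rose with both (84.5 for independent lists), 98 fell with both (50.1), 77 rose with LIGHT and fell with TGF-β1 (78.8), as VCAM1, TNFRSF1B, CSF1 and SOD2 did, and 51 fell with LIGHT and rose with TGF-β1 (53.7), as CTGF and BMP6 did. Both comparisons use the same 4 vehicle libraries. In 48 simulations with no effect of either cytokine, 0.146 genes on average were called the same way in both (at most 2). Only 0.56 genes with LIGHT and 0.83 with TGF-β1 were called there on average, so this count was bound to be small. It does not show how many of the 219 rest on the shared vehicle libraries. With the vehicle libraries split so that each comparison had its own 2, over 6 splits, 21 genes on average were called the same way (3 to 35, against 17.5 for independent lists) and 31 the opposite way (14 to 56, against 16.6). In these fits 84.3 genes on average were called with LIGHT. Both comparisons still drew on the LIGHT and TGF-β1 libraries of all donors through the donor block, so they were not independent. The covariance of the log2 changes across genes, which are not independent replicates, was 0.0910, the simulated covariance 0.0336 (0.0314 to 0.0354) and their difference 0.0573. The correlation was 0.178, against 0.469 in the simulations. The same-direction count was 18 without the donor block, 26, 33, 61 and 180 without donor 1, 2, 3 or 4, and 139 without the LIGHT library of donor 4.

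**Figure D4:**
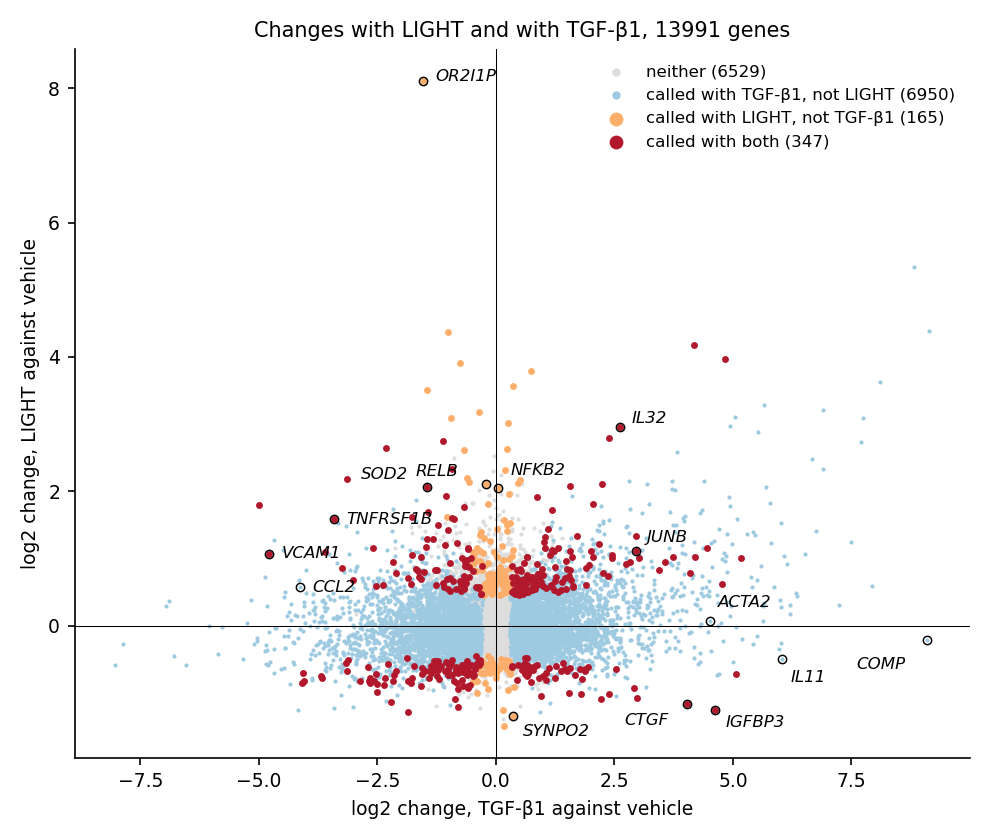
Log2 change with LIGHT against that with TGF-β1 for 13991 genes, coloured by the comparisons in which each passed the test, with counts in the legend. Circled genes are named; 219 genes were called in both comparisons in the same direction and 128 in opposite directions.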

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

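The test of reads counted on the opposite strand and the comparison of opposite-strand partners with the genes they overlap were chosen only after their results were seen, and the alternative without the LIGHT library of donor 4 after that library's values were seen. A sample was picked out when its gap to the nearest of the other 3 took up more of the group's range than 95% of random groups of 4 would give. Chance picks out about 1 in 20 groups. Among library measures 2 of 27 groups were picked out, among list medians 2 of 63 and among named genes 16 of 198.

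The LIGHT library of donor 4 held a count in 41398 genes, against 20290 to 22383 in the other LIGHT libraries. Depth is argued against, since at equal depth it held 1.98 times the genes of the next library, and a response to LIGHT as well, since 1 of the other 3 LIGHT libraries lay above all vehicle libraries at equal depth. Fragments spread evenly over the genome, as from genomic DNA, may be the source: in genes with no count elsewhere, counts rose with exon length with a log slope of 0.932 (1 if even). That background came to 14.5% of the library's counts.

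Genes higher with LIGHT lay mostly in exons overlapped on the opposite strand (75.7% against 49.5% of genes tested). The background in the LIGHT library of donor 4 is argued against as the cause, since the share was 73.4% without it. Counting of reads on the strand opposite to their own may contribute. Over 524 pairs, antisense genes held a median of 5.04 times the counts per kb of overlap that their host held per kb of exon. The ratio was above 1 in 82.6% of pairs, which argues against counting of reads on their own strand for them. All counts of the antisense gene were divided by its overlapped length, at least 50% of its exons. Whether a smaller share of reads from the other strand in the LIGHT libraries adds to this is not settled. Antisense genes moved above their hosts with LIGHT in 4 of 4 donors (medians 0.251, 0.374, 0.478 and 0.501 in donors 1 to 4). This met the limit set beforehand, a median of at least 0.1 in all 4. With TGF-β1 they moved less in each donor, up in donors 2 to 4 (0.16 to 0.21) and not in donor 1 (-0.048). Of the genes called with TGF-β1, 49.8% of the higher and 48.4% of the lower were overlapped. As 52.2% of all genes tested were called there, these shares lie near that of all genes in any case and decide little. Higher expression of the gene on the opposite strand cannot be told apart: the partners' median log2 change of 0.173 (upper quartile 0.334) lay below the 0.662 of the 65 genes overlapped over at least 50% of their exons by an expressed coding gene, but with reads counted on the opposite strand a partner's counts would not measure its expression.

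Extracellular matrix genes were lower with LIGHT, most in donor 4 (list median -0.86). Background counts in that library are argued against as the whole cause. Without it the list was still lower, with medians of -0.265, -0.139 and -0.310 in donors 1 to 3. The highest median of the other donors was -0.139, which fell short of the limit set beforehand. A bias by exon length and expression level is argued against. Without that library the median was -0.309, and 95% of matched random lists lay between -0.138 and 0.0272. An effect of LIGHT shared by the donors may remain, with a camera adjusted p of 3.47e-05 without that library, though with an estimated correlation it was 0.326.

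The other values were single donors apart from the other 3, with no explanation tested. The 10 most abundant genes took 17.4% of the TGF-β1 library of donor 4 (others 21.0 to 21.3%). Between LIGHT and TGF-β1, donor 1 had a median of -0.43 for TGF-β pathway components (others -0.69 to -0.65) and -1.70 for endoplasmic reticulum stress genes (others -1.53 to -1.51). With LIGHT, EGLN3 was at 4.54 in donor 4 (others at most 2.09), PLA2G4C at 1.66 in donor 3 (others 3.15 to 3.22) and IL6 at -1.47 in donor 1 (others 0.89 to 1.10), as log2 changes. With TGF-β1, donor 4 differed in ACTG2 (4.52), SMAD6 (-3.26), HLA-E (-1.05), MADCAM1 (-1.97), TNFSF4 (3.22), SMAD9 (-2.22) and NOTCH3 (2.91), donor 2 in COL1A1 (2.16), CCL2 (-2.79), DCN (-1.44) and KCNJ8 (-2.81), donor 1 in TMEM37 (-4.25) and donor 3 in IFIT1 (-3.22).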

How the results depend on the processing

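Leaving out the LIGHT library of donor 4, thinning to the shallowest library and keeping only genes without opposite-strand overlap were chosen only after the data were seen. The count of genes changed by LIGHT was 78 without the donor block, 89, 118, 169 and 440 without donor 1, 2, 3 or 4, 104 without overlap and 117 at 2-fold, against 512. It was 468 with RLE factors (460 of the same genes), 662 without the filter (354), 628 with DESeq2 (439), 592 by library size alone (446) and 383 without the LIGHT library of donor 4 (318). Without the filter the median of all genes moved to 0.79 with LIGHT, 0.15 with TGF-β1 and 1.26 between them. That fit took in 12570 genes counted in the LIGHT library of donor 4 and in none of the other 11. Their share in the shift was not tested. Genes changed by TGF-β1 numbered 3672 without overlap and 3595 at 2-fold, and genes differing between LIGHT and TGF-β1 3728 and 3789, partly because fewer genes were tested or kept; under the other alternatives they ranged from 5652 to 9187 and from 5868 to 9494. Genes called the same way in both were 18 without the donor block, 26 to 180 without 1 donor, 139 without the LIGHT library of donor 4 and 43 without overlap, against 219. With an estimated correlation 2 lists were called with LIGHT, 1 with TGF-β1 and 1 between them, against 9, 11 and 17; under the other alternatives run the numbers were 8 to 12, 11 to 15 and 14 to 17. Lists were not refitted by library size alone, with DESeq2 or without overlap.

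Scaling by library size alone reversed NFKB2 (-0.51), RELA (-0.11) and CLU (-0.14) with TGF-β1, and RELA (0.058) between LIGHT and TGF-β1; no other named gene reversed under any alternative run. Without the donor block 19 named genes lost their call with LIGHT, C3, VCAM1 and ICAM1 among them, and 15, 10, 8 and 5 did so without donor 1, 2, 3 or 4. NFKB2, RELB, BIRC3, TRAF2, SOD2, IL32, TNFRSF1B and PSME2 kept their call with LIGHT in all alternatives run for them (NFKB2 log2 change 1.95 to 2.14). JUNB, CTGF, PLA2G4C, TRIM47 and OR2I1P did so too. DESeq2 gave BIRC3 and PLA2G4C no adjusted p. SOD2, PSME2, JUNB, CTGF, PLA2G4C, TRIM47 and OR2I1P have opposite-strand overlap and were left out of the fit without it. Some named genes were too low in counts to be tested in an alternative, such as DSP without donor 4 and OR2I1P when thinned. The cause of these changes was not tested, apart from the smaller numbers of libraries or genes. Thinned to the shallowest library, 478 genes were called with LIGHT, 5652 with TGF-β1 and 5868 between them.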

Other observations

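The measurements of overlapping gene pairs below were chosen only after the result was seen, and the counts over other groupings of the libraries were planned. On the opposite strand of OR2I1P lies UBD (chromosome 6, 29555515 to 29559925, minus strand), an inflammation-inducible ubiquitin-like gene; they share 836 bases, 76.9% of the exons of UBD. OR2I1P had 1358 counts with LIGHT, 8 with vehicle and 2 with TGF-β1, and UBD had 1 count in all libraries. ACTA2-AS1 had 206608 counts and ACTA2 89701, and VIM-AS1 had 260813 and VIM 142121. These pairs share 16.2% of the exons of ACTA2-AS1 and 32.2% of those of VIM-AS1, less than the pairs that follow. Across 524 pairs the antisense gene held a median of 5.04 times the counts per kb of overlap that its host held per kb of exon. These pairs shared at least 50% of the antisense exons. The ratio was above 1 in 82.6% of them, which argues against counting of reads on their own strand for these pairs. A candidate explanation is that reads were counted on the opposite strand. The rise listed for OR2I1P could then belong to UBD, or to GABBR1, whose exons also overlap it on the opposite strand. In that case the counts of all genes, NFKB2 and COMP included, would be reads of the minority strand, and whether these keep the levels and changes of the genes was not tested.

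Other groupings of the 8 libraries of each comparison were fitted with the donor block, 32 of them (3 more could not be fitted). Of these, 8 part all 4 donor pairs, as the real one does, which is too few for a share under 5%. Among these 8 splits, the genes changed by LIGHT were 682 in the real one and at most 0 in another (1 of 8 as large), by TGF-β1 7479 and at most 0 (1 of 8; edgeR in each case), and between LIGHT and TGF-β1 6407 and at most 0 (1 of 8). The number of lists called was 10 with LIGHT and at most 9 in another (1 of 8), 11 with TGF-β1 and at most 14 (3 of 8), and 17 between them and at most 16 (1 of 8). The other 24 groupings put both libraries of at least 1 donor into the same group, and gave at most 3, 0 and 0 genes and 11, 16 and 17 lists. The number of lists called with the preset correlation thus did not tell the real grouping from the others. Groupings close to the real one keep part of its contrast. A camera call with that setting alone therefore does not tie a list to the treatment. Of 100 groupings of all 12 libraries, 4 gave as many genes called the same way in both comparisons (219, at most 5813), the real one included; the larger counts, several times the real one, point to a structure of the samples, the 4 TGF-β1 libraries standing together as the control.

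The genes called in both comparisons were weighed against their shared vehicle libraries. Over 6 choices of separate donors for the 2 comparisons, the covariance of the log2 changes was 0.0368 (0.0192 to 0.0658), and with the same donors 0.0720. With the vehicle libraries split it was 0.0477 (-0.0225 to 0.0990). In that fit the 2 comparisons still shared LIGHT and TGF-β1 libraries through the donor block.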
